A study of Mus musculus with 6 samples.

How the data were processed

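RNA of cells labelled MC3T3-E1, a preosteoblast line from mouse calvaria, was sequenced. There were 3 untreated control samples and 3 samples given 200 µM sulfasalazine for 24 h. The labels do not say whether a vehicle was used in either group. Group and replicate number came from the sample titles. Per the labels' protocols the reads were paired-end Illumina NovaSeq reads, the RNA was extracted with a kit sold for plant tissue, and the library kit was combined with an rRNA depletion kit for bacteria. All 6 samples carry the same batch label. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

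Per the submitters' processing notes, fastp 0.23.0, HISAT2 2.2.1, HTSeq 0.13.5, edgeR and the mouse build mm39 were used by the submitters. The roles and order of these tools are not given in the sources used here. The authors deposited 1 table of 14003 genes with an FPKM value per library (fragments scaled to gene length and mapped fragments, per the file headers). The same deposited table holds a library-size-adjusted signal per library, which is not a whole number of reads. After scaling by 1 factor per library, 100.0% of its low values in control replicate 1 lay within 0.1 of the reads recovered below. In control replicate 3 this held for 58.3% and in sulfasalazine replicate 1 for 69.3%, so the signal is not simply a scaled count in every library. The same table also holds the authors' log2 fold change and the authors' p-value and adjusted p-value for each gene. A second deposited table repeats, row for row, the 4891 genes that the authors selected at adjusted p under 0.05 and an absolute log2 fold change above 1. Of the 13994 genes that matched GENCODE release M21, 13861 had the start and end of that release, which is on GRCm38, although the processing notes name mm39. Coordinates are therefore given as GRCm38. Of the matched genes, 99.7% are annotated as protein coding, and other gene classes were not analysed here.

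Relative depth was recovered from the FPKM values, and whole reads were sought near the authors' adjusted signal. After scaling the FPKM by 1 factor per library, the 6 values of each gene were whole multiples of a common step. This held within 0.00001 reads for 100.0% of the values above 0. For 1499 genes more than 1 set of whole reads was possible, and the set nearest to the authors' adjusted signal was taken. The recovered reads on genes numbered 19613109, 20828706 and 15980935 in control replicates 1, 2 and 3, and 21579133, 19852472 and 19247900 in sulfasalazine replicates 1, 2 and 3. No 2 libraries agreed within sampling noise: the closest pair, sulfasalazine replicates 1 and 2, had a chi-square of 6.55 per degree of freedom, and all 6 libraries were kept as separate samples.

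Genes with at least 1 FPKM in at least 3 of the 6 libraries entered the test, which left 10338 genes. Values were taken as log2(FPKM + 1), so fold changes of genes with low values are understated. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of adjusted p under 0.05. Values are given as mean ± SD over the 3 libraries of a group in FPKM, and log2 fold changes are sulfasalazine over control with their standard error (SE). Before the data were examined, 33 gene lists and 18 key genes were fixed. Lists with at least 5 tested members, 28 in all, were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and the rotation test fry were the alternatives. Recovered reads and principal components were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, or in R.

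The rule for named genes was also fixed before the data were examined. It takes the 6 rises and the 6 falls with the largest log2 fold change among genes past the threshold whose groups do not overlap and whose higher group mean is at least 5 FPKM, leaving out predicted genes (names of Gm and digits, names ending in Rik, Ensembl identifiers, and pseudogenes marked -ps). It adds every key gene in the table, called or not, and up to 4 called members per list with the largest absolute change. For a list with no called member it allows up to 2 members with the highest mean. Genes named outside the rule are marked where they appear, except under other observations, where such genes were chosen after the data were seen.

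The gene test and camera were tested on simulated data, in 5 simulations of sulfasalazine against control with an assumed dispersion of 0.02. With 200 changed genes among 10000 to 10014 run, limma recovered 97% of genes changed by 1 on the log2 scale. It recovered 100% of those changed by 2 and called 0.12% of unchanged genes. Camera called a list of raised genes in 5 of the 5 simulations and an unchanged list in 0. Far fewer genes changed than the 66.5% called in the data, and genes were drawn independently with no outlying library. The simulations therefore could not show how correlation between genes affects camera. Named genes were checked for sequence shared with other genes in GENCODE M21, as exonic bases lying in another gene and as 50-base words found in transcripts of another gene. Reads of such genes cannot be assigned with certainty, and strand use in the counting is not given in the sources used here.

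The alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, no intensity trend, the replicate number as a block, each library left out, a threshold of 0.01 and a minimum absolute log2 fold change of 1. Chosen after the data were seen were limma voom on the recovered reads, replicate 3 of both groups left out, lists without shared members, and the overlap with the authors' table under every setting. Count models other than voom were not run, because no column holds deposited counts.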

Results

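Sulfasalazine is an anti-inflammatory drug and a known inhibitor of the cystine transporter whose light chain is encoded by Slc7a11. The series title concerns the binding of TNFα to its receptor TNFR1, NF-kB signalling and fracture healing, and the labels name no added TNFα. They call the controls untreated and name no vehicle, and an effect of a drug solvent was not tested. Gene expression was compared between 3 untreated samples and 3 given 200 µM sulfasalazine for 24 h, at 15980935 to 21579133 recovered reads per library. The cells are labelled MC3T3-E1, a preosteoblast line. Of 21 osteoblast markers with values, 12 had a mean below 1 FPKM and 6 had 10 FPKM or more, a point taken up below. The first principal component held 88.6% of the variance and separated the groups. Control replicate 3, with the fewest reads, scored -42.6 on it, against -65.3 and -63.2 for control replicates 1 and 2 and 54.1 to 59.2 for the sulfasalazine libraries.

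**Figure D1:**
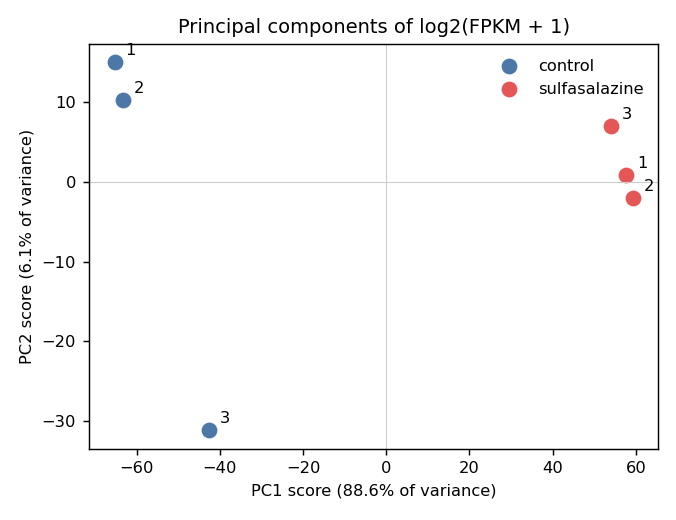
Scores of the 6 libraries on the first principal component (horizontal axis, 88.6% of the variance) and the second (vertical axis, 6.1%), computed on log2(FPKM + 1) of the tested genes; each point is a library, coloured by group and marked with its replicate number. Control replicate 3 lies at -31.2 on the second component, below the other 5 libraries.

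Sulfasalazine-treated cells had higher expression of 3846 genes and lower expression of 3032 among the 10338 tested, which is 66.5% of them (limma, Benjamini-Hochberg adjusted p under 0.05). The steepest falls included genes for inflammatory mediators. Lcn2, encoding lipocalin 2 (chromosome 2, 32384633 to 32388252), fell from 632 ± 586 to 4.77 ± 6.50 FPKM (SD, n = 3 per group), by 7.02 on the log2 scale (SE 0.83, limma adjusted p = 0.00016). Traf1, a signalling adaptor of TNF receptors (chromosome 2, 34941750 to 34961772), fell from 116 ± 34.2 to 0.224 ± 0.0307 FPKM (log2 fold change -6.54, SE 0.23). The chemokine gene Cxcl2 fell from 170 ± 107 to 0.630 ± 0.319 FPKM, and Csf2, encoding the cytokine GM-CSF, from 30.1 ± 19.7 FPKM to 0.0565, 0 and 0 FPKM in the 3 sulfasalazine libraries. Soat2, a cholesterol esterification enzyme, fell from 126 ± 24.3 to 2.42 ± 1.11 FPKM. Fosl1, an AP-1 subunit, fell from 3407 ± 191 to 134 ± 35.4 FPKM; 57.2% of its exonic bases lie in other genes, mainly Ccdc85b on the opposite strand.

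Among the largest rises, Gsta4, a glutathione transferase (chromosome 9, 78182774 to 78209349), rose from 1.37 ± 0.775 to 148 ± 13 FPKM (log2 fold change 6.03, SE 0.23, limma adjusted p = 2.4e-06). Gstm1, another glutathione transferase, rose from 1.46 ± 0.878 to 88.2 ± 4.17 FPKM, with 18.9% of its 50-base words found in other genes. Scd2, a fatty acid desaturase (chromosome 19, 44293674 to 44306864), rose from 29.0 ± 9.22 to 1645 ± 213 FPKM, a log2 fold change of 5.81 (SE 0.21). Bmf, a pro-apoptotic BCL2-family gene, rose from 0.881 ± 0.131 to 82.5 ± 11.5 FPKM. The creatine synthesis gene Gamt rose from 0.122, 0.228 and 0 FPKM in the controls to 40.3 ± 2.80 FPKM, and the tight-junction gene Cldn2 from 5.17, 7.33 and 21.5 FPKM in control replicates 1, 2 and 3 to 363 ± 21.7 FPKM (log2 fold change 5.12, and 5.67 without control replicate 3). Over all tested genes, the 3 values of one group lay wholly above those of the other for 7378, where chance gives 10% (1034 genes). An exact permutation test of 3 against 3 cannot go below p = 0.1 for a single gene.

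**Figure D2:**
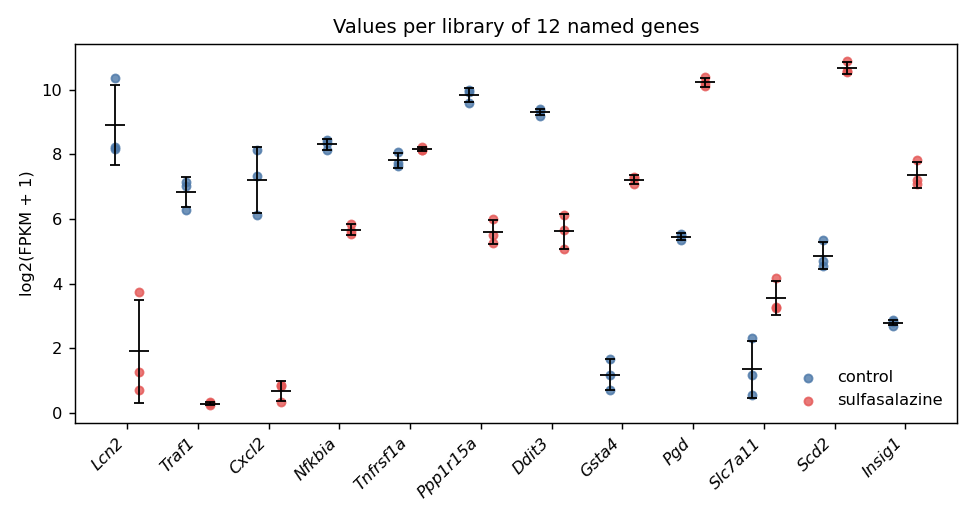
Expression per library of 12 named genes (vertical axis, log2(FPKM + 1)) in control (blue) and sulfasalazine (red) libraries; points are libraries, horizontal bars the means and whiskers the SD over 3 libraries. Traf1 lies between 77.5 and 142 FPKM in the controls and at 0.253 FPKM or less with sulfasalazine, and Tnfrsf1a differs least among the 12.

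The title names NF-kB signalling, and NF-kB target genes were lower with sulfasalazine. Of 36 tested members, 32 fell, 1 rose (Birc2, an apoptosis inhibitor, named after its value was seen) and 3 did not pass; the counts adjusted over the list alone were 32 and 1. The 4 largest falls were those of Lcn2, Traf1, Cxcl2 and Csf2. The median log2 fold change of the list was -2.35, and camera gave an adjusted p of 2.4e-11 at the preset correlation. With an estimated correlation the call was lost (adjusted p = 0.449). Control values of several members were uneven: Lcn2 stood at 287, 301 and 1308 FPKM in control replicates 1, 2 and 3. Its values were also uneven in sulfasalazine replicates 1, 2 and 3, at 1.41, 0.635 and 12.3 FPKM. Other splits of the 6 libraries into groups of 3 gave up to 17 lists past the preset-correlation threshold, against 10 for the real one. Each of those splits mixed treated and untreated libraries unequally, so part of the treatment difference remained. Their list counts are therefore not a chance level.

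Components of the TNF receptor and NF-kB pathway moved in both directions, 10 of 33 higher and 17 lower, with the same counts adjusted over the list alone. Nfkbia, encoding the inhibitor IκBα (chromosome 12, 55489410 to 55492647), fell from 317 ± 35.5 to 50.1 ± 6.10 FPKM (log2 fold change -2.64, SE 0.13). Tnfaip3, encoding the NF-kB inhibitor A20, fell from 31.2 ± 8.18 to 1.27 ± 0.284 FPKM and the NF-kB subunit gene Relb from 105 ± 9.71 to 13.2 ± 2.29 FPKM. The subunit genes Nfkb1 and Rela fell by 1.39 and 1.17 on the log2 scale. Ikbkg, encoding the kinase regulator NEMO, rose from 8.15 ± 0.192 to 91.9 ± 1.79 FPKM. Of its exonic bases 5.2% lie in other genes, mainly G6pdx on the opposite strand, so part of its reads may belong to G6pdx. The list median was -0.64 (camera adjusted p = 0.027), and the call was lost with an estimated correlation (adjusted p = 0.623) and without replicate 3 of both groups (adjusted p = 0.11). Of the 35 listed components 13 are also in another list, and this list was not tested without them. Nfkbia, Tnfaip3, Relb, Nfkb1 and Rela are also NF-kB target list members, so the result is not separate from that of the targets.

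Tnfrsf1a, encoding TNFR1 (chromosome 6, 125349362 to 125362484), stood at 227 ± 37.2 FPKM in controls and 287 ± 12.6 FPKM with sulfasalazine (log2 fold change 0.35, SE 0.13, limma adjusted p = 0.046). That call was lost under median-of-ratios scaling (adjusted p = 0.19), without the filter or the trend, and when any 1 library other than control replicate 3 was left out (adjusted p = 0.098 to 0.15). Tnfrsf1b, encoding TNFR2, rose from 61.9 ± 14 to 86.2 ± 5.58 FPKM (log2 fold change 0.49, adjusted p = 0.024), a call also lost under median-of-ratios scaling (adjusted p = 0.083) and when any 1 of control replicates 1 and 2 or sulfasalazine replicates 1 and 2 was left out (adjusted p = 0.06 to 0.09). Tnf was listed at 0.129, 0.0302 and 0.236 FPKM in the controls and at 0 in all 3 sulfasalazine libraries, and Il6 at 0.554 ± 0.269 and 0.0654 ± 0.0605 FPKM; both were below the filter and were not tested in the main fit. With no filter, Il6 passed (log2 fold change -0.53, adjusted p = 0.0083) and Tnf did not (-0.17, adjusted p = 0.056), while the authors' deposited table has both lower at an adjusted p under 0.05. Ccl2, encoding a monocyte chemokine, fell from 26.3 ± 16.1 to 0.547 ± 0.818 FPKM (log2 fold change -4.04, adjusted p = 0.00028). Slc7a11 rose from 1.90 ± 1.83 to 11.4 ± 4.81 FPKM, a log2 fold change of 2.21 (SE 0.44, adjusted p = 0.0025).

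Targets of the integrated stress response were lower, with 40 of 50 tested members falling and 3 rising, the same counts adjusted over the list alone. Ppp1r15a, a phosphatase subunit that reverses the response, fell from 916 ± 133 to 48.3 ± 13 FPKM. Ddit3, encoding the transcription factor CHOP, fell from 637 ± 45.7 to 50.4 ± 18.5 FPKM, with 10.9% of its exonic bases in another gene entry. The cytokine gene Gdf15 fell from 109 ± 24.3 to 4.91 ± 4.01 FPKM. Atf4, the other factor whose targets the list holds and an osteoblast list member, fell from 1394 ± 93.3 to 392 ± 131 FPKM (log2 fold change -1.88, SE 0.22, limma adjusted p = 0.00014). The 3 rises, named after their values were seen, were the haem oxygenase gene Hmox1, the mTOR inhibitor gene Ddit4 and Slc7a11. The list median was -1.58 (camera adjusted p = 1.5e-09; adjusted p = 0.623 with an estimated correlation). Genes of the ER chaperone and unfolded protein response list split, 13 higher and 10 lower of 31 (camera adjusted p = 0.97); the chaperone gene Hspa5 fell from 1317 ± 344 to 398 ± 72.7 FPKM, and Edem2, of ER-associated degradation, rose from 24.0 ± 3.70 to 77.2 ± 4.31 FPKM.

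NRF2 targets and glutathione genes were higher: 36 of 39 rose and 1 fell, Nfe2l2, which encodes NRF2 itself (named after its value was seen). Adjusted over the list alone, 36 rose and 2 fell. Besides Gsta4 and Gstm1, Blvrb, encoding biliverdin reductase B, rose from 5.82 ± 1.38 to 206 ± 2.05 FPKM and Pgd, of the pentose phosphate pathway, from 43.0 ± 3.07 to 1206 ± 122 FPKM. The median was 1.93 (camera adjusted p = 7.0e-10; adjusted p = 0.449 with an estimated correlation). Among ferroptosis and iron genes 11 of 27 rose and 8 fell (camera adjusted p = 0.76). The ferritin light chain gene Ftl1 rose from 2783 ± 485 to 18020 ± 2377 FPKM, with 50.9% of its 50-base words found in other genes, and the prostaglandin synthase gene Ptgs2 fell from 412 ± 128 to 76.3 ± 20.9 FPKM.

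Sterol biosynthesis genes were higher, 24 of 27 rising and 0 falling, the same counts adjusted over the list alone. Insig1, a feedback regulator of sterol synthesis, rose from 5.94 ± 0.387 to 169 ± 49.7 FPKM and the reductase gene Tm7sf2 from 3.55 ± 0.472 to 106 ± 8.98 FPKM, with 12.1% of the exonic bases of Tm7sf2 in another gene. The median was 2.08 (camera adjusted p = 1.6e-08; adjusted p = 0.623 with an estimated correlation). All 15 tested fatty acid synthesis genes rose, also adjusted over the list alone, with a median of 1.81 (camera adjusted p = 5.2e-06; adjusted p = 0.623 with an estimated correlation). They included Scd2, the desaturase gene Fads2, from 36.8 ± 16.0 to 632 ± 139 FPKM, and the regulator gene Srebf1, from 30.1 ± 5.6 to 237 ± 18.3 FPKM.

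**Figure D3:**
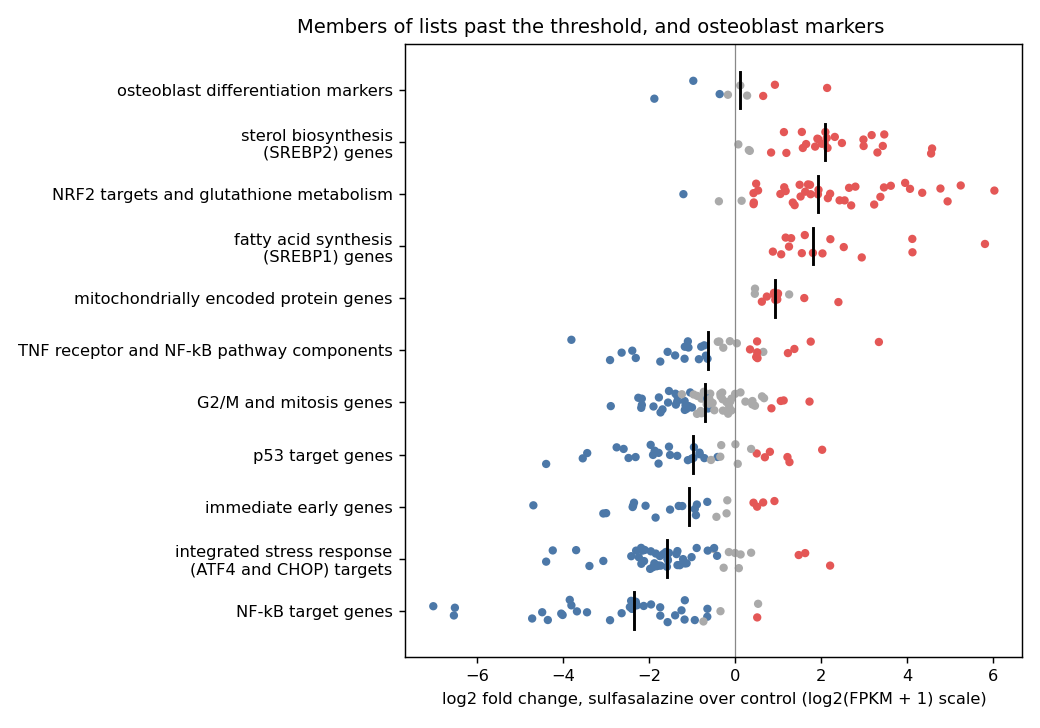
Log2 fold changes (horizontal axis, sulfasalazine over control on the log2(FPKM + 1) scale) of the tested members of the 10 gene lists past the camera threshold and of the osteoblast markers (vertical axis, one row per list); red and blue points passed the gene test as higher and lower, grey points did not, and black bars are list medians. NF-kB targets have the lowest median, -2.35, and sterol genes the highest, 2.08.

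Immediate early genes fell in 15 of 22 cases and rose in 4 (median -1.08, camera adjusted p = 0.0002; adjusted p = 0.623 with an estimated correlation), with Atf3, a stress-induced transcription factor gene, falling from 233 ± 56.4 to 27.8 ± 11.3 FPKM. Of 35 p53 targets 23 fell and 6 rose (median -0.97, camera adjusted p = 0.00046; adjusted p = 0.739 with an estimated correlation); the kinase gene Plk2 fell from 421 ± 76.0 to 37.5 ± 2.06 FPKM. Of 67 G2/M and mitosis genes 24 fell and 4 rose, or 21 and 4 adjusted over the list alone (median -0.69, camera adjusted p = 0.00084; adjusted p = 0.916 with an estimated correlation). Fry did not call the G2/M list either (adjusted p = 0.24), and the estimated correlation between its members was 0.81. The mitotic kinase gene Aurka fell from 107 ± 8.22 to 24.4 ± 11.5 FPKM. For immediate early genes and p53 targets the counts adjusted over the list alone were the same as those over all genes. Mitochondrially encoded genes took 1.47% to 2.21% of the reads in controls and 3.72% to 3.80% with sulfasalazine; 10 of 13 rose and 0 fell, also adjusted over the list alone, mt-Nd5 from 597 ± 85.0 to 1818 ± 198 FPKM. Their median was 0.94 (camera adjusted p = 0.017; adjusted p = 0.623 with an estimated correlation), and the call was lost under quantile normalization (adjusted p = 0.06) and without control replicate 3 (adjusted p = 0.061).

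Osteoblast markers ranged from near 0 to abundant in both groups. Of 36 listed, 21 were in the table, 12 of them with a mean below 1 FPKM and 6 with 10 FPKM or more, and 9 were tested, of which 3 rose and 3 fell, the same adjusted over the list alone (median 0.12, mean 0.08, camera direction down, adjusted p = 0.97). Col1a1, encoding the main collagen of bone, stood at 0.0561, 0.132 and 0.651 FPKM in the controls and 0.178, 0.550 and 0.655 FPKM with sulfasalazine. Bglap, encoding osteocalcin, stood at 0.454 ± 0.344 and 0.364 ± 0.121 FPKM, and 56.6% of its 50-base words occur in other genes. Sp7, encoding osterix, was listed at 0 in 5 libraries and at 0.0724 FPKM in sulfasalazine replicate 2, and Tnfrsf11b, encoding osteoprotegerin, at 0.0390 ± 0.0244 and 0.0240 ± 0.0416 FPKM. Runx2, an osteoblast transcription factor gene, stood at 23.5 ± 2.2 and 18.1 ± 1.57 FPKM (log2 fold change -0.36, SE 0.13, adjusted p = 0.044), a call lost when any 1 of control replicates 1 and 2 or sulfasalazine replicates 1 and 2 was left out (adjusted p = 0.11 to 0.16). Spp1, encoding osteopontin, fell from 1868 ± 309 to 947 ± 104 FPKM (log2 fold change -0.97, SE 0.17), and 18.8% of its exonic bases lie in another annotated gene. The key genes Alpl, Ibsp and Tnfsf11 were not in the table of 14003 genes and were not analysed here, so their expression cannot be judged.

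Among epithelial markers, 5 of 12 in the table were tested, of which 2 rose and 1 fell (camera adjusted p = 0.74). Of the 12, 7 had a mean below 1 FPKM and 3, all keratin genes, 10 FPKM or more. Krt8, with 26.9% of its 50-base words in other genes, rose from 287 ± 33.4 to 902 ± 58.1 FPKM. Krt19 fell from 350 ± 43.2 to 154 ± 42.9 FPKM. Krt18 stood at 708 ± 61.1 and 913 ± 61.4 FPKM (limma adjusted p = 0.031). That call was lost under median-of-ratios scaling (adjusted p = 0.17) and without replicate 3 of both groups (adjusted p = 0.066). It was also lost without control replicate 1 or any 1 sulfasalazine library (adjusted p = 0.053 to 0.13). For the 5 other marker lists fewer than 5 members were tested and no list test was made. Chondrocyte markers had 1 fall among 2 tested (Sox9, from 158 ± 6.74 to 34.8 ± 7.08 FPKM), skeletal muscle markers 1 fall of 1, fibroblast and pericyte markers no call of 2, macrophage and osteoclast markers 1 rise and 1 fall of 3, and endothelial markers 1 rise of 2. Of the fibroblast and pericyte markers, Pdgfrb passed as lower under median-of-ratios scaling (limma adjusted p = 0.046) and quantile normalization (0.020). It also passed without sulfasalazine replicate 3 (0.018) and without replicate 3 of both groups (0.001). Ly6a passed as lower under median-of-ratios scaling (0.049) and without control replicate 1 (0.029).

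**Figure D4:**
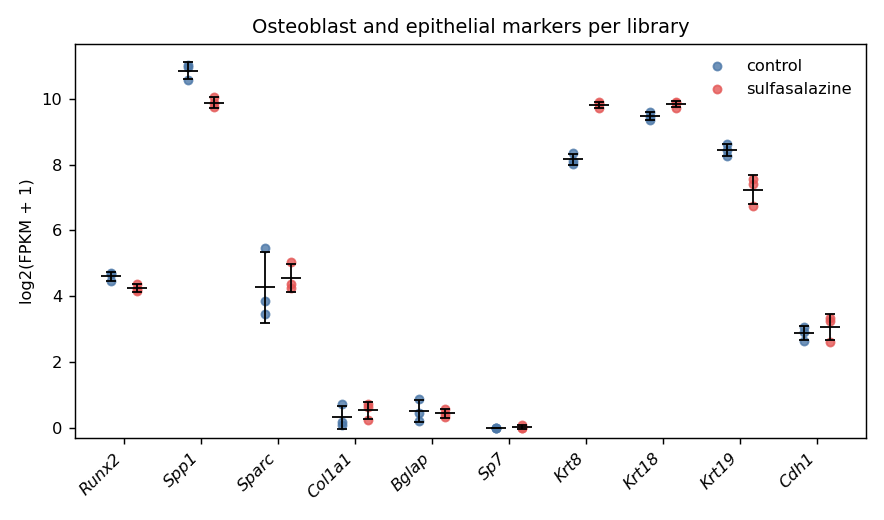
Osteoblast markers (left 6) and epithelial markers (right 4) per library, as log2(FPKM + 1) on the vertical axis, in control (blue) and sulfasalazine (red) libraries; points are libraries, horizontal bars the means and whiskers the SD over 3 libraries. Col1a1 stays below 0.7 FPKM in all 6 libraries, whereas Krt18 lies between 654 and 961 FPKM.

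The other lists did not pass camera. Heat shock genes had 12 of 20 higher and 5 lower (adjusted p = 0.091), with Hspa8, a constitutive chaperone gene, rising from 246 ± 42.9 to 2394 ± 123 FPKM; 38.6% of its 50-base words occur in other genes. Hypoxia and glycolysis genes had 18 of 32 higher and 5 lower (adjusted p = 0.068), with the phosphofructokinase gene Pfkl rising from 24.7 ± 12 to 260 ± 61.3 FPKM. Folate and one-carbon genes had 3 of 21 higher and 11 lower (adjusted p = 0.091). Osteoclast-coupling factors had 2 of 7 higher and 3 lower (adjusted p = 0.31), Csf1, encoding the macrophage growth factor M-CSF, falling from 708 ± 105 to 33.6 ± 5.05 FPKM. Collagen and matrix assembly genes had 11 of 21 higher and 6 lower (adjusted p = 0.74), the inhibitor gene Timp1 falling from 276 ± 33.6 to 51.6 ± 1.45 FPKM. TGF-beta and BMP targets had 8 of 15 higher and 3 lower (adjusted p = 0.31), and Wnt targets 3 of 9 in each direction (adjusted p = 0.57), Myc falling from 658 ± 31.6 to 128 ± 6.03 FPKM.

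The remaining lists gave 7 higher and 17 lower of 51 for G1/S and DNA replication genes (adjusted p = 0.35), 3 and 8 of 33 for interferon-stimulated genes (adjusted p = 0.21), and 24 and 11 of 61 for nuclear-encoded oxidative phosphorylation genes (adjusted p = 0.31). Cytosolic ribosomal protein genes gave 12 and 14 of 71 (median -0.05, mean 0.01, adjusted p = 0.52), lysosome and autophagy genes 15 and 21 of 47 (adjusted p = 0.13), and adipocyte markers 3 and 3 of 7 (adjusted p = 0.85). Aryl hydrocarbon receptor targets gave 3 and 2 of 7 with a median of -0.34, a mean of 0.73 and the camera direction up (adjusted p = 0.97). Adjusted over the list alone, the higher and lower counts were 11 and 7 for collagen and matrix genes, 7 and 15 for G1/S genes, 3 and 7 for interferon-stimulated genes and 10 and 9 for ribosomal protein genes, and the same as over all genes for the others. Single libraries or settings decided some of these list tests. Without sulfasalazine replicate 3, hypoxia and glycolysis (adjusted p = 0.013), folate (0.041), interferon-stimulated (0.041) and G1/S genes (0.045) passed camera. Without control replicate 1, folate (0.028) and ribosomal protein genes (0.049) passed, and without sulfasalazine replicate 1, heat shock genes (0.049). Heat shock genes also passed with no filter (0.043), with a filter of 5 FPKM (0.042) and under quantile normalization (0.038), under which hypoxia and glycolysis (0.021) and oxidative phosphorylation genes (0.042) passed too. Without replicate 3 of both groups, hypoxia and glycolysis (0.013) and oxidative phosphorylation genes (0.04) passed.

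The authors' deposited table selected 2632 genes as higher and 2259 as lower. Of the 4891 genes selected in the authors' deposited table, 3979 were tested in the refit and 3923 passed it, each in the same direction. Across the tested genes the log2 fold changes of the refit and of the authors' deposited table had a Spearman correlation of 0.995; genes are not independent replicates, and both come from the same libraries.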

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

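The direction of change held for every named gene and list past its threshold, wherever it was tested, under the 13 alternatives fixed before the data were examined and the 2 fits chosen after they were seen (voom on recovered reads, and replicate 3 of both groups left out): 0 reversed. Counts stayed within 1.5 times the reported value except as follows. Requiring an absolute log2 fold change of at least 1 left 3430 of the 6878 genes, by construction. Camera with an estimated correlation called 0 of 28 lists, against 10 at the preset correlation; 2 lists had an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 19. The NF-kB target median of -2.349 then lost its call (camera adjusted p = 0.449), and the estimated correlation between its members was 0.161. Camera at the preset correlation gave this list an adjusted p of 2.4e-08 or less under the other fixed alternatives. Without replicate 3 of both groups camera gave 8.6e-08. Fry gave the list an adjusted p of 0.00036. Leaving out 1 library gave 5496 to 7622 genes. Among the 18 key genes 9 were called, and 6 to 9 with 1 library left out, the losses being among Tnfrsf1a, Tnfrsf1b and Runx2. With the replicate number as a replicate block 6420 genes and 7 of the key genes were called. Tnfrsf1a and Runx2 lost their calls there, as did the keratin gene Krt18. The deviations of same-numbered libraries correlated at 0.036, -0.194 and -0.174 and no library correlated best with its own number, so the numbers were not taken to pair samples. Median-of-ratios scaling moved the median of all genes by -0.117, from 0.083 to -0.034, and the higher share of calls from 55.9% to 49.3%; 94.1% of the reported calls remained. Voom called 6910 genes, with 99.1% of the reported calls among them. Without genes that another list holds, the NF-kB median was -2.43 over 20 members. The count tests planned for recovered reads were not run, as no deposited column holds counts. The filter, not depth, kept 3665 genes out of the test; with no filter 7409 of 14003 were called. Depth limits genes with few reads.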

Other observations

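The tests in this part were chosen after the results were seen, except that the scaling alternatives and the gene lists were fixed before the data were examined. Of 9 genes often used as references in quantitative PCR, some moved and some did not. Gapdh, a glycolytic enzyme gene, stood at 96.0 ± 11.9 FPKM in controls and rose by 2.00 on the log2 scale (SE 0.28, limma adjusted p = 0.00036), and the isomerase gene Ppia rose by 1.7 and the lysosomal gene Gusb by 1.61. Hprt and B2m fell by 0.55 and 0.74. These 5 directions and calls held under both scaling alternatives; the rise of Actb, 0.74, lost its call under quantile normalization (0.38, adjusted p = 0.08). Ywhaz, at -0.32, also lost its call there (adjusted p = 0.077). Rplp0 passed under none of the 3 settings (log2 fold change 0.31, 0.19 under median-of-ratios scaling and -0.28 under quantile normalization; adjusted p = 0.21, 0.51 and 0.12), and neither did Tbp, with a log2 fold change of 0.05 (SE 0.12), or -0.07 under either scaling. Of the 50-base words of Rplp0, Gapdh, Ywhaz, Ppia and Actb, 33.1%, 24.7%, 15.2%, 12.7% and 9.1% occur in other genes, and 19.0% of the exonic bases of Tbp lie in Pdcd2, on the other strand.

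A search of 105 gene symbol families with at least 10 tested members gave 0 past the camera threshold (smallest adjusted p = 0.096; 16 at an unadjusted p under 0.05), and fry called 60. The real grouping gave 6878 genes and the highest of the other 9 splits 0 (limma; up to 480 at an unadjusted p under 0.05, and 0 with voom); 1 of the 10 splits reached the real count. For lists at the preset correlation, 8 of the 10 splits, the real one included, gave 10 or more, and the highest other gave 17. With 10 splits the share cannot go below 0.1, too few for a decision on chance in either case. Each other split also placed treated and untreated libraries in both of its groups. The treatment difference then widened the spread within groups, which lowers the gene counts. Part of it also stayed between the groups and could reach the list tests. The other splits therefore give no chance level for genes or lists.

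Of the 21 osteoblast markers in the table, 12 had a mean below 1 FPKM, among them Col1a1, Bglap and Sp7. By contrast, 6 had a mean of 10 FPKM or more, including Spp1, Atf4, Ank, Bmp4 and Runx2. Depth does not account for the low ones: at the median level of all genes, 9.85 FPKM, these 12 markers would have had a median of 388 reads, whereas the median seen was 3 and the highest 63. A second candidate explanation is another cell type or line in the cultures. Of the 12 epithelial markers in the table, 3, all keratin genes, had a mean of 10 FPKM or more, while Cldn7, Krt5 and Krt14 stayed below 0.3 FPKM and 11 of 13 fibroblast and pericyte markers had a mean under 1 FPKM. The epithelial cadherin gene Cdh1 stood at 6.42 ± 1.11 FPKM in controls and the collagen gene Col3a1 at 0.121 ± 0.188 FPKM. Of genes outside the lists, the mesenchymal filament gene Vim stood at 397 ± 83.5 FPKM and the intestinal transcription factor gene Cdx2 at 9.60 ± 2.85 FPKM. No expression profile of the labelled line was at hand, and the feature is shared by both groups, so this explanation cannot be told apart from the state of the line itself.

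Control replicate 3 lay at 0.21 of the way from the other controls to the sulfasalazine libraries. Its lower depth does not account for that, since control replicates 1 and 2 thinned to its 15980935 reads lay at -0.01 and 0.01. Admixed sulfasalazine RNA would move every gene by one share of the linear difference. Among 1155 genes at least 4-fold apart, 15.7% moved the other way (6.9% by more than the gap between control replicates 1 and 2), and the median share was 0.082 for higher and 0.344 for lower genes. No biological explanation was tested, since the labels give none for this library.

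The fall of the NF-kB targets may reflect several processes. A few genes took more of the reads with sulfasalazine (8.23% to 9.27% in the top 10 genes, against 4.28% to 4.61%), but median-of-ratios scaling, which would bring back a fall from this cause, took the list median from -2.349 to -2.471, away from 0. A loss of short-lived transcripts as a class could lower NF-kB, stress-response and immediate early genes together. Of the 22 immediate early genes 15 fell and 4 rose, Dusp6, Nr4a1, Nr4a2 and Klf2 (named after their values were seen). Without transcript half-lives such a loss cannot be told apart from an effect on NF-kB. The treatment itself, as the biological explanation, stays open.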
